A study of Corynebacterium glutamicum R with 10 samples.

How the data were processed

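Total RNA from wild-type and rshA deletion mutant cells of Corynebacterium glutamicum R was measured on 1-colour arrays. Per the labels' protocols, the cells grew in a nutrient-rich medium with 1% glucose, as 100 ml cultures in 500 ml flasks at 33 °C, and cDNA was made from 10 µg of total RNA and labelled with Cy3. The labels give 5 arrays per strain, numbered 1 to 5, and the series text calls the experiments independent without saying whether each number stands for a separate culture. The p-values therefore measure the spread between these samples.

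The deposited scanner files hold spot intensity values. Per the file headers, the processed signal is the intensity after background subtraction and spatial detrending by Agilent Feature Extraction version 10.5.1.1, while the submitters' processing notes give version 10.5.5.1. The files also hold, per the file headers, the median pixel intensity of each spot and of its local background, and other columns with flags of 0 or 1 for spots well above background, saturated spots and outlier spots. No genome build is given in the sources used here. Of 45220 spots, 1417 controls were left out, and 43803 spots of 40204 probes remained. These were 3278 numbered probes (3092 with 2 spots and 186 with 3), 36911 strand probes with 1 spot each, and 15 probes of a further named set with 10 spots each. Spots flagged as outliers, 35 to 346 per array, were left out, and 0 spots were saturated.

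The deposited value table holds log2 values of the same arrays, whose making is not described in the sources used here. Set against the scanner files, each pair of columns with 1 replicate number sums to 0 for every probe, and 2 times the mutant column equals the log2 difference between a mutant and a wild-type array plus a constant (r = 1). For replicates 1, 4 and 5 these are the arrays of that number. The columns of replicate 2 match wild-type array 2 with mutant array 3, and those of replicate 3 match wild-type array 3 with mutant array 2, which share slides. The strain of each column is not affected. The table's column medians lie between -0.06 and 0.06. Its 40264 rows include 60 controls, and 40204 matched the probes. The direction is mutant minus wild type, the scaling constant between arrays remains unknown, and the table served as an alternative only.

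The main values were log2 of the processed signal minus each array's 75th percentile of it, averaged over the spots of a probe. The 75th percentile lay between 3373 and 6139 intensity units, which is 141 to 242 times the median background. Probes were tested if well above background (more than a 0.5 share of their spots) on at least 5 of the 10 arrays, without regard to strain. Numbered probes and strand probes were tested separately with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, strain as the only term) and Benjamini-Hochberg adjustment within each set, at an adjusted p of 0.05. At an unadjusted p under 0.05, 310 numbered probes passed. A probe not well above background on any array of a group has only a bound there: the bright group's mean against the dim group's mean of, per array, the higher of the lowest signal among probes well above background and the probe's own signal. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 served for the other steps.

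The identifiers name no gene. The reference table of another strain of the species, with 3079 genes, matched 0 of them. The rule fixed beforehand named rshA, sigH, the 15 probes with the largest rise and the 10 with the largest fall among separated probes, and members of 27 gene lists. Without names, the lists, rshA and sigH were not run, and the text names only the first 2 of each direction. The numbers of the probes are used as an order, since the signals of strand probes with adjacent numbers correlated (r = 0.79 forward and 0.80 reverse, across probes, which are not independent replicates). Forward signals correlated negatively with the reverse probes taken in reversed order (r = -0.53) and not in the same order (r between 0.05 and 0.10 over the offsets tried), so the reverse numbering was read from its end. That probe numbers follow the genome is an inference from these values.

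The arrays lay on 4 slides and were scanned on 3 dates, each holding both strains: 2 arrays in scan 1, 4 in scan 2 and 4 in scan 3. The first principal component of the numbered probes, 62.3% of the variance, separated scan 3 from the others, and the second, 20.1%, separated the strains. With strain in the model, limma called 965 numbered probes higher and 1066 lower in scan 3 than in scan 1. The pairing by replicate number was checked by correlating deviations from the group means: the correlations of same-numbered arrays were 0.86, 0.46, 0.74, 0.79 and 0.86. All exceed the limit of 0.1 set beforehand, so by that rule the numbers were taken as pairs. The main fit nevertheless held strain as its only term, so its p-values do not use the pairs. In limma the replicate number entered as a block in an alternative only. Arrays of different numbers in scans 1 and 2 also correlated, between 0.30 and 0.67. Wild type 2 correlated more with mutant 3 (0.64), its slide mate, than with mutant 2, while wild type 3 correlated more with mutant 3 (0.74) than with its slide mate mutant 2 (0.67), and wild type 5 more with mutant 4 (0.93) than with mutant 5. The check therefore does not separate the pairing from scan date or slide, and does not show that the numbers rather than the slides pair replicates 2 and 3. The pairing comes from the numbers in the labels.

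The model was tested on simulated data with 3237 numbered probes, 5 runs and 200 seeded changes. The noise was drawn independently for each probe around the scan-date shifts of the real arrays. The shares below therefore do not cover probes that move together or a single array that departs from its group. Without a block it recovered 8.4% of changes of 0.5 on the log2 scale, 62.4% of changes of 1 and 91.2% of changes of 2, and 0.153% of the calls were false. With scan date as a block it recovered 65.2%, 91.2% and 98.8%, and 5.84% of the calls were false.

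The alternatives fixed before the data were examined were quantile normalization, the array median in place of the 75th percentile, the percentile over probes detected on all arrays, no filter or a filter on all 10 arrays, eBayes with trend and robust, array weights, the replicate number, slide or scan date as a block, and leaving out each array. Chosen after seeing the data were the crossed pairing of replicates 2 and 3, leaving out each scan date, the median over the spots of a probe, the deposited table as paired differences, and normexp with an offset of 50 on the median signal, because the scanner columns lack the mean signal that the plan named. Segments of numbered probes were scanned with log2 fold changes limited to 2 in size and at least 10 probes per segment.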

Results

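Transcript levels of Corynebacterium glutamicum R, a Gram-positive soil bacterium used for industrial amino acid production, were measured in wild-type cells and in a mutant that lacks rshA. RshA is known as the anti-sigma factor of SigH, an alternative sigma factor of RNA polymerase that serves the response to heat and oxidative stress. Both strains were sampled in the exponential phase, with 5 arrays per strain from experiments that the submitters call independent. Each of the 10 arrays carried 1 sample labelled with Cy3. The arrays hold 3278 numbered probes, each printed as 2 or 3 spots, and 36911 strand probes printed once, of which 18462 are named for the forward and 18449 for the reverse strand. The files do not pair these identifiers with gene names, so the deleted gene, sigH and the gene groups chosen beforehand are not reported, and at most 2 identifiers per direction are named. Signals were strong: between 98.4% and 99.6% of the numbered probes and between 84.2% and 94.3% of the strand probes were well above background on each array. The number of arrays limits the precision of every comparison.

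The comparison asked which transcripts differ between the rshA deletion mutant and the wild type during exponential growth. More numbered probes were higher than lower in the mutant, and more of the rises than of the falls reached 4-fold. Of 3238 numbered probes tested with limma, with strain as the only term, 78 were higher and 31 were lower at a Benjamini-Hochberg adjusted p under 0.05. At least 2-fold changes made up 60 of the higher and 19 of the lower probes. The higher probes rose 2.82-fold at the median, with log2 fold changes from 0.49 to 3.55, with 22 probes up at least 4-fold and 9 up at least 8-fold. The lower probes had a median log2 fold change of -1.10, and 2 of them were down at least 4-fold. In 77 of the 78 higher probes and 22 of the 31 lower probes, all 5 mutant arrays lay on one side of all 5 wild-type arrays. Over all numbered probes tested 4.69% were separated in this way, against 0.794% by chance.

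**Figure D1:**
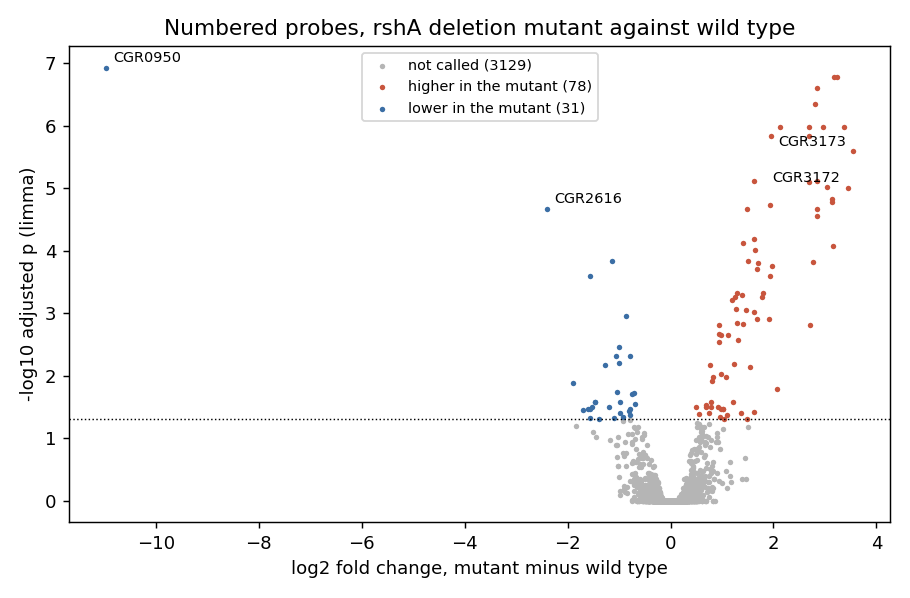
Log2 fold change of each numbered probe (x axis, mutant minus wild type, 5 arrays per group) against the negative log10 of its limma adjusted p (y axis), with the 0.05 threshold as a dotted line. The 78 higher probes reach a log2 fold change of 3.55, and among the 31 lower probes CGR0950 stands far to the left of the others.

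CGR3173 rose from a log2 signal of -0.76 ± 0.32 in the wild type to 2.79 ± 0.41 in the mutant (SD, n = 5 each, relative to the 75th percentile of the array). This is an 11.7-fold rise, with a log2 fold change of 3.55 (SE 0.23) and a limma adjusted p of 2.58e-06. CGR3172, the probe with the preceding number, rose 10.8-fold, from -0.61 ± 0.39 to 2.83 ± 0.47 (SD, n = 5), with a limma adjusted p of 9.88e-06. CGR0950 was well above background on all 5 wild-type arrays, at 0.89 ± 0.97 (SD, n = 5), and not well above background on any mutant array. Its fall has only a bound, at least 608-fold, from the wild-type mean against the mean, over the mutant arrays, of the lowest signal well above background, and its limma adjusted p was 1.18e-07. The size depends on the background handling: the fitted log2 fold change was -10.96, and -6.86 with normexp and an offset of 50. CGR2616 fell 5.28-fold, from -0.85 ± 0.29 to -3.25 ± 0.34 (SD, n = 5), with a limma adjusted p of 2.12e-05.

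**Figure D2:**
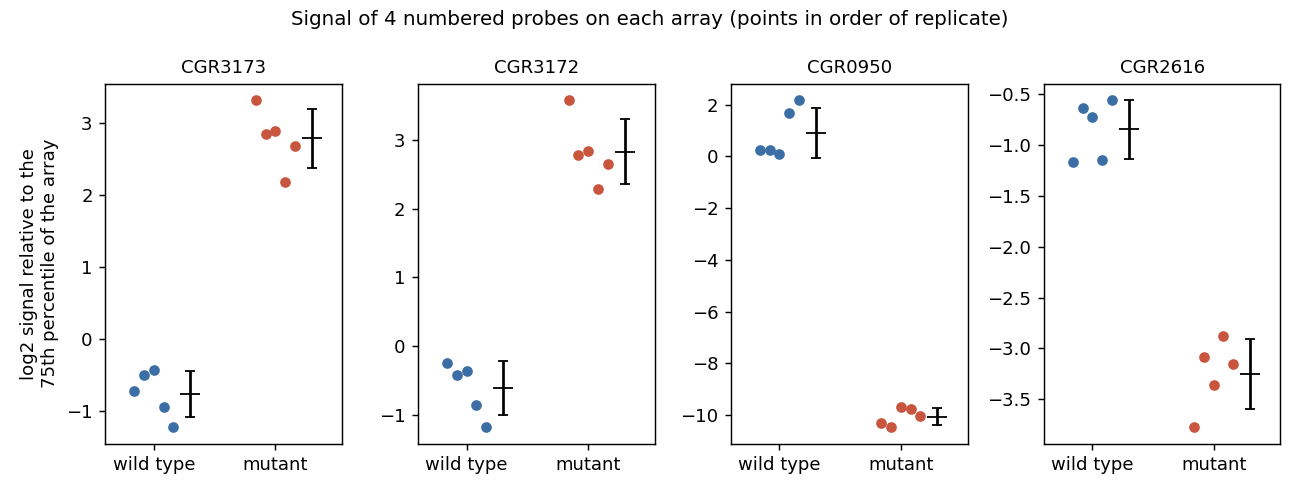
Log2 signal (y axis, relative to the 75th percentile of the array) of 4 numbered probes on each of the 5 wild-type and 5 mutant arrays, with the mean and SD beside the points. No mutant value overlaps a wild-type value, and CGR0950 lies between -10.48 and -9.71 on the mutant arrays, where it was not well above background.

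CGR0950 was the only numbered probe of the 3278 that was well above background on all wild-type arrays and on no mutant array. No numbered probe showed the opposite change. The 3 probe numbers on either side of it had log2 fold changes between -0.25 and 0.06, and none of these passed the limma test. Among the strand probes, 1 forward probe went from 0.62 ± 0.77 in the wild type to -9.40 ± 2.01 in the mutant (SD, n = 5) and was well above background on 1 of the 5 mutant arrays, a fall of at least 362-fold. A reverse probe went from -4.80 ± 1.19 to -10.31 ± 0.31 (SD, n = 5) and was well above background on none, a fall of at least 11.7-fold. Of the strand probes, 5 forward and 4 reverse were well above background on all wild-type and no mutant arrays, among them 2 forward probes at 69.46% and 69.47% of the numbering with falls of at least 2.39-fold and 7.71-fold. The opposite change, from no wild-type to all mutant arrays, was seen in 3 forward and 2 reverse probes. The forward and the reverse probe described above, which have the largest lower bounds of the lost strand probes, both lie at 29.27% of the length of their strand's numbering, counted from the first forward and from the last reverse probe, and CGR0950 lies at 28.98% of the numbered probes. Of the 3 probes on either side of the forward one, the log2 fold changes ranged from -0.48 to 1.91, and of those beside the reverse one from -0.09 to 2.23, and none of these passed the limma test.

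**Figure D3:**
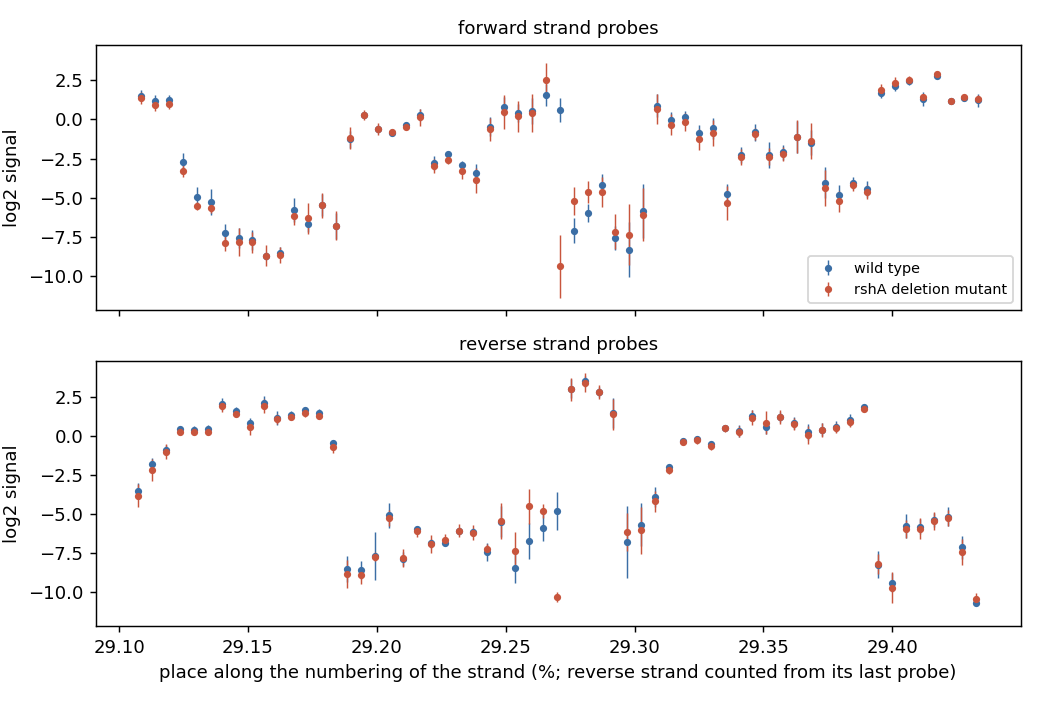
Log2 signal (y axis, mean and SD of 5 arrays per group) of consecutive forward and reverse strand probes along the numbering of each strand (x axis, percent of the probes of that strand, the reverse strand counted from its last probe). At 29.27% 1 probe on each strand drops in the mutant to -9.40 and -10.31.

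The probes that changed were grouped along the numbering. Of the 78 higher numbered probes, 34 lay in 13 runs of at least 2 consecutive numbers, against at most 14 in 1000 shuffles (permutation p = 0.001, the smallest they can give). The longest such run held 4 probes. Of the 31 lower probes, 15 lay in runs, against at most 7 in the shuffles (permutation p = 0.001), but 9 of these 15 lay among the numbers 3202 to 3278, where the calls depended on single arrays, and 6 lay elsewhere. The strand probes gave the same direction at finer spacing: of 33163 tested with limma, 413 were higher and 55 were lower, 386 and 40 of them at least 2-fold. The higher strand probes split into 210 forward and 203 reverse probes, with median log2 fold changes of 2.10 and 1.65. Runs of at least 3 consecutive numbers held 179 of the higher forward and 165 of the higher reverse probes, against at most 4 and 6 in the shuffles (permutation p = 0.001 for each). The longest run held 25 forward probes, with a median log2 fold change of 2.76. All these shuffles moved probes and not arrays, so their p-values do not measure the spread between samples. Signals of adjacent probes correlate (r = 0.39 numbered, 0.79 forward and 0.80 reverse), and neighbours that move together for any reason would give such runs. The runs therefore describe the grouping and are no test of a strain effect.

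The 31 lower numbered probes were spread unevenly. The highest numbers, 3202 to 3278, held 15 of them. A scan for the segment with the lowest mean log2 fold change picked these 77 probes out of all numbered probes (permutation p = 0.01 over 100 shuffles, the smallest they can give). In this block 74 of the 77 probes had a fold change below 0 and the median was -0.67, against -0.03 for the other numbered probes. The block was chosen for its low mean, so these values describe it and are no further test. The shuffles moved probes and not arrays, so their p does not measure the spread between samples. The median differences between the mutant and the wild-type array of the same number were -1.07, -0.77, -1.04, -0.0016 and -0.96 for replicates 1 to 5, so that the block was lower on 4 of the 5 mutant arrays and at the wild-type level on mutant replicate 4. With the replicate number as a block 36 of the 77 probes were called lower, against 43 numbered probes outside, and with scan date as a block 39 against 74. With slide as a block these counts were 35 and 77, and with array weights 47 and 51. The calls within the block depended on single arrays: 41 of the 77 probes were called lower without mutant replicate 4, 5 without wild-type replicate 5, and 2 without any other single array, against 8 to 14 outside the block in those 8 fits. Without the arrays of scan 1 or of scan 2, 0 were called in the block and 11 or 2 outside it, and without those of scan 3 the counts were 43 and 19.

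**Figure D4:**
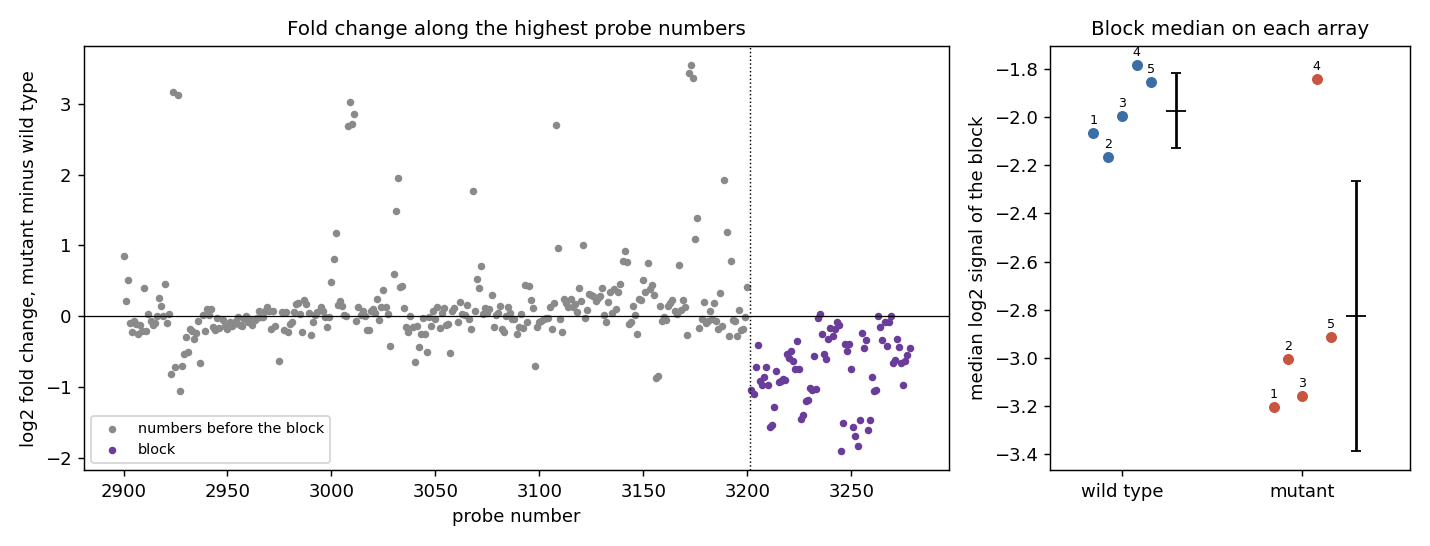
Left, log2 fold change (y axis, mutant minus wild type) of the numbered probes along the highest probe numbers (x axis), with the block of 77 probes in purple. Right, median log2 signal of the block on each array (y axis, points numbered by replicate, mean and SD beside them): mutant replicate 4 lies at -1.84, among the wild-type arrays, and the other mutant arrays between -3.21 and -2.92.

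The arrays were scanned on 3 dates, each with equal numbers of both strains, and scan 3 stood apart from the others along the first principal component. With scan date as a block, limma called 208 numbered probes higher and 113 lower, and with the replicate number as a block it called 157 higher and 79 lower. For the strand probes these counts were 985 and 282 with scan date, and 651 and 122 with the replicate block. All 109 numbered probes called without a block were also called, in the same direction, in each of these blocked fits. Each block held equal numbers of both strains and left the fold changes as they were, so the shared direction is no check. All 109 also had the same sign of change within each of the 3 scan dates, which is no independent check, since they were chosen over the same arrays and in 99 of them the strains do not overlap. Within scan 2, with 2 arrays per strain, limma called 110 numbered probes higher and 62 lower, and within scan 3, also with 2 per strain, 54 and 5. Scan 1 held 1 array per strain and has no test. The number of lower probes depended on single arrays: leaving out any 1 array other than mutant replicate 4 gave 10 to 16 in place of 31, and leaving out mutant replicate 4 gave 57. The number at least 2-fold lower moved alike, to between 6 and 10 or to 36 in place of 19. The lower strand probes numbered 35, 34 and 35 in place of 55 without wild-type replicate 2, wild-type replicate 4 and mutant replicate 5.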

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

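The tests on the lost probe, on dim signal alone and on wild-type RNA in mutant replicate 4 were chosen after the results were seen. In 20 groups of 5 arrays, 3 held an array far from the other 4, and chance alone gives about 1 in 20.

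The median log2 signal of the block of the highest probe numbers was -1.84 on mutant replicate 4 and between -3.21 and -2.92 on the other mutant arrays. Over the 5 mutant arrays it averaged -2.83 ± 0.56, against -1.97 ± 0.16 in the wild type (SD, n = 5 each; two-sided exact permutation p = 0.0625 over the 5 pairs, the smallest they can give, and 0.0397 over all 10 arrays without pairing, both on a block chosen from the same data). Wild-type RNA in mutant replicate 4 could account for its level only if the lost numbered probe had reappeared there, and its signal was at most 0.17% of the wild-type mean.

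The lowering of the block itself has 4 candidate explanations. Its spots were spread over the array, with an SD of rows 0.95 times that of all numbered spots, which argues against a local flaw. The block's median was -0.48 or lower in each of the 3 scan dates, so the lowering was not seen on one date alone. In scan 3 it came from replicate 5 (-0.96), with replicate 4 at -0.0016. The block was chosen for its low mean on these same arrays, so these medians are no independent test. The test set beforehand for dim probes went with that explanation. The 7 members in the upper part of the signal range had a median log2 fold change of -0.080 in place of -0.67. When fold changes were shuffled among probes of like signal and the scan repeated, 0 of 100 shuffles gave a segment as low (scan statistic -17.4, against -5.77 for the lowest shuffle). Dim probes that vary independently therefore do not account for the block. These shuffles break up neighbours, so they cannot exclude an effect of dim signal shared by adjacent probes. Of the 77 members, 75 were well above background on all 10 arrays, with a median of -0.71. The members that were not called had a median of -0.56, so the lowering was not confined to the called members. The call depends on the fit, and with scan date as a block 39 of the 77 were called lower. This median therefore does not settle whether only some transcripts are regulated. What stays open is an effect of dim signal shared by adjacent probes, regulation of some transcripts, or a shared change of this stretch in 4 of the 5 mutant samples. A shared change could be a lower copy number or a common regulator. The link to the deletion also stays open, since mutant replicate 4 lacks the lowering. A lower copy number of the whole stretch would be expected to lower the 7 brighter members too, whose median was -0.080. The last runs of forward strand probes called, 18324 to 18334, 18412 to 18420 and 18428 to 18429, were higher, with medians of 3.32, 1.84 and 0.96. The last forward probe called lower was 17830, and the first reverse probe called, 455, was higher. Whether strand probes cover this stretch is not known. No test here separates these explanations.

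CGR0950 was lost from all 5 mutant arrays. The 2 lost strand probes with the largest lower bounds of their fall, on other spots and 1 on each strand, both lie at 29.27% of their numbering, and 0.58% of random places would be as near to them as CGR0950 at 28.98%, which argues against failed spots of that probe alone if the 3 numberings run in parallel. In all, 36 strand probes were well above background on every wild-type array and on at most 1 mutant array, mostly at other places, and the forward one of these 2 stayed above background on 1 mutant array. A candidate explanation, as a hypothesis, is that CGR0950 and these 2 probes lie in the deleted segment, but the identifiers do not say so. On the forward strand probe, mutant replicate 5 stood apart with a log2 signal of -5.87, while the other mutant arrays lay between -10.68 and -9.87.

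Wild-type replicate 2 had 346 spots left out as outliers, against 46 to 103 on the other wild-type arrays. In the set of 15 further probes with 10 spots each, which no comparison used, 2 were higher in the mutant on all 5 arrays, with log2 fold changes of 1.84 and 1.64 (limma adjusted p of 5.80e-05 and 6.91e-05), and the other 13 lay between -0.05 and 0.14.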

How the results depend on the processing

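The alternatives chosen after seeing the data were the crossed pairing, the deposited table, the normexp fit, the median over spots and leaving out a scan date. CGR3173, CGR3172 and CGR2616 kept their direction and an adjusted p under 0.05 in all 27 alternatives, with log2 fold changes of 3.42 to 3.70, 3.25 to 3.60 and -2.56 to -2.19. CGR0950 did so in the 18 alternatives that tested it, at -6.86 with normexp, whose offset of 50 raises dim signals, and between -11.05 and -10.31 in the others; 9 that left out a wild-type array or a scan date, or asked for signal on all 10 arrays, did not test it. In the fits with a block or another filter, these probes, where tested, have the fold changes of the main fit, so only the adjusted p could change. The mean signal that the planned normexp fit needed, the median over probes of a gene, the gene lists, rshA and sigH could not be run.

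The counts of numbered probes higher, lower and at least 2-fold lower were 78, 31 and 19. Array weights gave 177, 98 and 42, the slide as a block 199, 112 and 29, and the crossed pairing 170, 94 and 29. The replicate block gave 157 higher and 79 lower, scan date as a block 208 and 113, and the paired differences of the deposited table gave 168 and 84. Leaving out scan 1 gave 11 lower and 6 at least 2-fold lower, leaving out scan 3 gave 62 and 38, and leaving out scan 2 gave 35 higher, 2 lower, 35 at least 2-fold higher and 2 at least 2-fold lower. Leaving out one array gave 60 to 82 higher, 10 to 57 lower, 51 to 61 at least 2-fold higher and 6 to 36 at least 2-fold lower; 57 and 36 came without mutant replicate 4.

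For the 413 higher and 55 lower strand probes, the replicate block gave 651 and 122, the crossed pairing 744 and 191, the slide 978 and 401, scan date 985 and 282, and the deposited paired differences gave 728 and 149. Lower strand probes numbered 113 with array weights, 34 with the array median, 36 without scan 1 and 24 without scan 3. Without scan 2, 134 were higher and 5 lower. Leaving out one array gave 334 to 412 higher and 34 to 53 lower. Fits without scan 1, 2 or 3 or without an array have fewer samples; for the other alternatives the cause was not tested. The replicate block changed the call of none of the 4 named probes.

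Of 100 splits of the 10 arrays into 5 and 5, 5 called at least the 109 numbered probes of the real split, so chance cannot be excluded in this form. The highest other split called 1146 and, like the others above 109, set scan 3 apart, which points to a structure of the samples. Among 36 splits balanced over the scan dates, with scan date as a block, only the real 1 reached its 321 calls. The highest other called 0. A share of 1 in 36 is the smallest these splits can give, which argues against chance there without excluding it. Among the 16 splits that part all 5 pairs, without a block, the real one called 109 and the highest other 0. Here the smallest possible share is 1 in 16, so this count cannot exclude chance either. The splits above 109 in the first count part fewer pairs. Signal over background was high on every array and limited few numbered probes, but 84.2% to 94.3% of strand probes were well above background.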

Other observations

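The test on the opposite strand was chosen before its result was seen, and the comparison of the numbered with the strand probes after seeing both sets. In 100 equal bins of the numbering, the counts of higher numbered and higher strand probes correlated weakly across bins (r = 0.27). This was little above the 0.24 that was the highest of 99 shifts (permutation p = 0.01, the smallest they can give). The comparison takes the numberings to run in parallel. Bins are not independent replicates.

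Strand probes that rose at least 2-fold numbered 386, and 307 of them faced a tested probe on the opposite strand. If labelled cDNA had been copied onto the opposite strand, the facing probes could be expected to rise too. Their median log2 fold change was -0.11, which is -0.038 from the median of 1000 shifted positions, and 14 of the 307 were at least 2-fold higher. Among the tested facing probes the rise therefore stayed on one strand at most places, as copying of a large share would not predict. Facing probes that were not tested were left out. A small copied share could be hidden where the facing probe has signal of its own, so weak copying is not excluded.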
